A study of Potamopyrgus antipodarum with 3 samples.

How the data were processed

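Methylated DNA was measured in foot tissue of Potamopyrgus antipodarum, a freshwater snail that reproduces clonally, by methylated DNA immunoprecipitation followed by sequencing (MeDIP-seq). In this assay an antibody against 5-methylcytosine takes methylated fragments out of sheared, denatured DNA, so the read count over a stretch of sequence grows with the density of methylated cytosines and with the number of copies of that stretch. Per the labels' protocols, snails came from Ritter Island, on a spring-fed tributary of the Snake River, and founded 5 iso-female lines that were kept at 14 °C and a salinity of 2 to 4 ppt. Foot DNA of 10 snails of the first laboratory generation (F1) made 1 pool, about 6 µg of pooled DNA was sheared to a setting of 300 bp, and 5 µg of antibody was used. The group held 3 such pools, numbered 1 to 3 in the sample titles.

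The authors deposited 4 comparison tables, each setting the F1 pools against 1 other set of pools, and these sets are known here only by the names in the column headers: Lytle, Washington, SnakeMain and SnakeSide. The labels used here describe no samples under these names. They name a further table coded for F1, which was not used here, and do not name the SnakeSide table. Whether SnakeSide stands for another place is therefore left open. The 24 per-library columns of those pools (6 in each table) were therefore not used in any step, and no test between groups was refitted. The submitters' processing notes name FastQC, Trimmomatic, Bowtie2, SAMtools and edgeR, without versions; the genome build is not given in the sources used here. Per the file headers, each table lists 739509 consecutive windows of 100 bp on 1 sequence named as all contigs joined, 73.95 Mb long, so a position is an offset on that joined sequence and neighbouring windows can lie on different contigs. No annotation was used, and windows are named by start and end alone.

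Per the file headers, the authors gave for each window a read count and an RPKM value (reads scaled to window length and library size) for every library. The deposited counts of the F1 pools were whole numbers and were identical in the 4 tables. The deposited log2 values are a log2 fold change and a log2 mean CPM (count scaled to library size), and the deposited p-values are an unadjusted and an adjusted p from the authors' edgeR test. Between 152526 and 160088 windows per table carried a test. The deposited adjusted p equalled a Benjamini-Hochberg adjustment over the tested windows of the same table. Each table was normalised and tested on its own by the authors.

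The authors' fold changes were turned so that a positive value means more reads in F1. The order of the libraries in each header set the direction, and 5 forms of a check against the F1 counts were tried after the values had been seen. Comparing the sign of large fold changes (over 2 on the log2 scale) with the F1 level over the deposited mean level agreed in only 18.5%, 17.5%, 22.9% and 5.71% of windows of the Lytle, Washington, SnakeMain and SnakeSide tables. After a median offset was removed the shares were 99.3%, 97.8%, 89.1% and 54.4%, so this form left SnakeSide open. Rank correlation of that level difference with the fold change, in the 60730 windows with a summed F1 count of at least 50, ran from 0.914 to 0.941. Rank correlation of the F1 level itself with the fold change within 7 bands of mean level was negative in at least 1 band of the SnakeMain and SnakeSide tables, with lowest values of -0.263 and -0.199. The last form rebuilt the F1 level from the deposited mean level and fold change in both directions. Its residual SD for SnakeSide was 0.0919 with the direction used and 0.442 with the opposite one (log2 units). The residual SD was 0.0490 against 0.406 for Lytle, 0.0533 against 0.419 for Washington and 0.0667 against 0.347 for SnakeMain.

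From the F1 counts, CPM values were computed over the total window count of each pool. Windows with a summed count of at least 10 over the 3 pools (137333 windows) entered the comparison of pools. The spread was the common biological coefficient of variation from edgeR 4.0.16 in R 4.3.3, with an intercept and TMM factors. Applied to simulated counts with a coefficient of 0.1, 0.2 and 0.3 over these windows, the step returned 0.101, 0.199 and 0.300. Pairs of pools were set against counting noise by the chi-square of their counts per degree of freedom. Pools 2 and 3 showed no spread beyond the assumed counting noise, so their mean entered each mean ± SD as 1 replicate, giving n = 2. That noise was too wide at higher counts, so the chi-square cannot decide whether pools 2 and 3 are separate libraries. The authors' test treated all 3 pools as replicates. Labels call the pools separate samples; whether they shared snail lines is not stated, and the spread may be partly technical.

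Windows were called at an adjusted p under 0.05 in the authors' deposited tables, and called windows that touched and shared a direction were joined into regions. Because every table uses the same F1 pools, unchanged groups of 3 pools were simulated against them from a negative binomial with the F1 spread (3 runs of 4 groups, 18 pairs). None of the 12 simulated groups gave a call, so the number of calls they share is 0 by construction. For the overlap of calls, lists as long as the authors' lists were therefore taken from the simulated groups by smallest p in each direction over the 137333 covered windows, a step chosen after the data had been seen. With 200 of 137333 windows changed, the same step called 31.3% of windows changed by 1 log2 unit. It called 77.6% of those changed by 2 and 87.9% of those changed by 3, with 8 false calls. So few changed windows made the cutoff on the unadjusted p stricter than in tables with many calls. These shares therefore do not give the power of the authors' tests. Differences between 2 tables were tested per window with a standard error worked back from the deposited p-value and fold change, both tables taken as independent. The shared F1 counting error is thereby counted in each table, which by itself makes this approximate test conservative. Where the other pools held few or no reads, the worked-back standard error may be too small, so the test need not be conservative there.

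Named windows followed a rule fixed before the data were examined: in each table the 5 regions with the smallest p in each direction, windows called in every table, and the 5 windows with the highest mean F1 CPM whose CPM agreed within 2 times in all 3 pools. No window was called in every table. Lists of genes fixed beforehand, coverage against CpG content and genomic features were not analysed here, since they need a genome and annotation. Total window counts of 4167531, 5273194 and 4904316 set the precision: a count of 0 allows up to 0.720, 0.569 and 0.612 CPM in pools 1, 2 and 3 (3 counts), which covers counting error only. Alternatives covered count filters, normalisation, call thresholds, merging of regions and leaving out each pool. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used.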

Results

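Foot tissue of Potamopyrgus antipodarum, the New Zealand mud snail, was profiled by MeDIP-seq in 3 pools of 10 first-generation laboratory snails derived from Ritter Island. The series title frames the work as a study of how stable phenotype and DNA methylation are between generations of a clonal snail. The pools held total window counts of 4167531, 5273194 and 4904316. RPKM values placed these at 2775414, 3512509 and 3266764 reads, since a read was counted in 1.50 windows on average. All positions are offsets on the joined contig sequence, and no genes are paired with the windows.

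Reads of the F1 pools were concentrated in short islands. Copy number and unknown contig ends can shape these islands as well as methylation, and no unenriched DNA was used here. Of 739509 windows, 70.9% had no read in any pool, and the 18.6% with a summed count of at least 10 held 97.9% of all counts. These covered windows formed 35395 islands with a median length of 300 bp (quartiles 200 and 500 bp). The longest island spanned 4200 bp, at 129501 to 133700. The highest 10% of windows held 89.4% ± 0.819 of the counts of a pool (SD, n = 2), and the highest 1% held 32.9% ± 2.42.

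Counts reached exactly 300 in each pool and no more, in 17, 49 and 28 windows. With an implied read length of 51.1 bp, a 100 bp window has about 300 combinations of start position and strand, so 300 is the count at 1 read per start and strand. The highest F1 level, 300 counts in all 3 pools (65.5 CPM ± 9.16, SD, n = 2), was shared by 10 tied windows. The 5 named among them, an arbitrary choice within the tie, started at 2510001, 3704401, 30463301, 30509101 and 30748501. That SD follows from the totals of the pools alone.

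Across covered windows, which are not independent replicates, Pearson's r of log2(CPM + 1) was 0.947 for pools 1 and 2, 0.941 for pools 1 and 3 and 0.962 for pools 2 and 3. Much of this r rests on the range of levels. In windows with a summed count of 10 to 29 it was 0.152, 0.132 and 0.270 for the same pairs, and at 30 to 89 it was 0.483, 0.429 and 0.628. The common biological coefficient of variation was 0.0785. The chi-square per degree of freedom was 0.843 for pools 2 and 3, against 1.37 for pools 1 and 2 and 1.43 for pools 1 and 3. For pools 2 and 3 it was 0.997 at summed counts of 1 to 9, 0.984 at 10 to 29 and 0.893 at 30 to 89. The assumed counting noise was thus too wide at higher counts, and these values and the coefficient may be too low. They show that pools 2 and 3 were closer to each other than to pool 1. Whether pools 2 and 3 are separate libraries cannot be decided from them. Pools 2 and 3 were counted as 1 sample here. Without pool 1 the coefficient dropped to 0.00988, and with pools 2 and 3 summed to 1 library it was 0.124. The authors' deposited p-values treat the 3 pools as separate.

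In the authors' deposited Lytle table, F1 differed from the Lytle pools in 8342 of 160088 tested windows (edgeR, adjusted p under 0.05). F1 was higher in 4664 of them and lower in 3678. The windows joined into 3002 regions with F1 higher and 2288 with F1 lower, the longest being 1000 bp at 2284901 to 2285900, with F1 higher. The median log2 fold change in the authors' deposited table was 1.55 for the higher windows and -0.94 for the lower ones. Windows with F1 higher thus had larger fold changes, of at least 1 log2 unit in 75.2% against 43.9% of the lower ones.

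The region with the smallest p in the authors' deposited Lytle table, at 73236101 to 73236400, had its centre at 73236201 to 73236300. There the F1 pools held 99, 111 and 112 reads (22.8 CPM ± 1.28, SD, n = 2). The authors' deposited log2 fold change was 9.69 over Lytle (edgeR, adjusted p = 9.82e-78). Fitted values of this size depend on the prior count wherever the other pools held few or no reads, and they are not bounds. The next regions with F1 higher were centred on windows starting at 33289301, 3631301, 2103601 and 42442701, with log2 fold changes of 7.47, 8.53, 8.19 and 4.90 in the authors' deposited table. Among regions with F1 lower, the smallest p fell at 18921801 to 18921900, with a log2 fold change of -1.55 in the authors' deposited table (edgeR, adjusted p = 8.14e-13). The remaining named ones started at 64510801, 17460301, 26038401 and 30505801, with -1.96, -1.07, -1.57 and -0.77 in the same authors' deposited table. The last region ran for 700 bp, from 30505401 to 30506100.

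**Figure D1:**
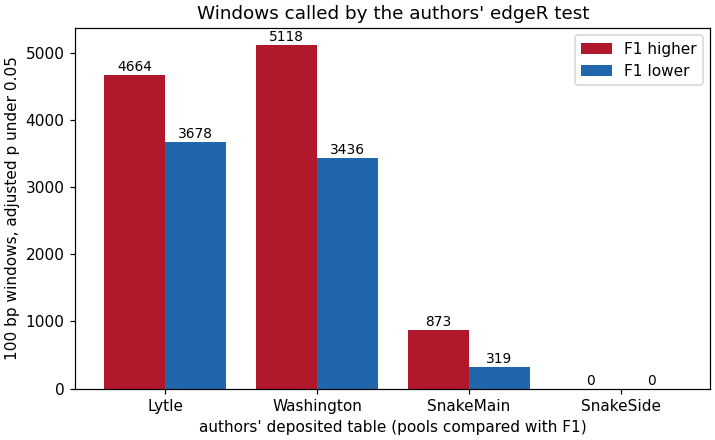
Bars give the number of 100 bp windows called at an adjusted p under 0.05 in each of the authors' deposited tables, with F1 higher (red) or lower (blue) than the named pools. The Lytle and Washington tables held 8342 and 8554 calls, SnakeMain 1192 and SnakeSide 0.

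The authors' deposited Washington table held 8554 called windows of 159162 tested (edgeR, adjusted p under 0.05), 5118 with F1 higher and 3436 with F1 lower. They formed 3274 and 2156 regions. Median log2 fold changes in the authors' deposited table were 1.56 and -0.89. The windows starting at 73236201, 33289301 and 3631301 were again among the 5 regions with the smallest p, with log2 fold changes of 9.66, 6.62 and 5.76 in the authors' deposited table. The window at 73086501 to 73086600 differed over Washington alone. With 62, 83 and 76 reads in the F1 pools, it had an authors' deposited log2 fold change of 3.41 over Washington (edgeR, adjusted p = 1.97e-34) and 0.22 over Lytle (adjusted p = 0.549). The difference between those tables had an adjusted p of 1.29e-20 in the approximate test on edgeR results. The window at 869001 to 869100 was higher in F1 by 4.08 in the authors' deposited Washington table. The smallest p with F1 lower was at 30752201 to 30752300, with -1.42 (edgeR, adjusted p = 2.87e-14 in the authors' deposited table). Other named windows with F1 lower started at 18071401, 52665301, 64510801 and 45803101 and lay between -1.34 and -2.28 in the authors' deposited table. The region around 18071401 was the longest with F1 lower, 900 bp from 18070901 to 18071800.

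Against SnakeMain, whose name carries that of the Snake River, fewer windows passed the test. The authors' deposited table held 1192 called windows of 158635 tested (edgeR, adjusted p under 0.05), 873 with F1 higher and 319 with F1 lower. These made 672 and 263 regions, the longest of 500 bp. Median log2 fold changes were 1.52 and -0.95 in the authors' deposited table. The test had less power than the one against Lytle: at a log2 mean CPM of 2 to 4 and an absolute log2 fold change of 1 to 1.5, the median unadjusted p in the authors' deposited SnakeMain table was 5.90 times that in the Lytle table. The ratio was 1.39 for Washington and 19.4 for SnakeSide, so counts of calls are not on 1 scale across tables. Large fold changes were also fewer. At the same mean level and after centring by level, 2.87% of SnakeMain windows reached an absolute log2 fold change of 1, against 5.14% for Lytle. All 5 named regions with F1 higher had been named against Lytle or Washington as well: 73236201, 869001, 33289301, 2103601 and 3631301. Their log2 fold changes in the authors' deposited SnakeMain table were 3.06, 2.82, 2.46, 3.58 and 3.06. At 73236201 the fold over SnakeMain was smaller than that over Lytle (adjusted p of the difference = 1.64e-25, approximate test on edgeR results). That p may be too small, since the Lytle fold of 9.69 may depend on the prior count. With F1 lower, the named windows started at 47385101, 25214701, 825201, 31839201 and 19711401. Their log2 fold changes ran from -0.74 to -3.20 in the authors' deposited table. The windows at 25214701 and 31839201 held no more than 3 reads in any F1 pool.

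No window was called in the authors' deposited SnakeSide table, where the lowest adjusted p was 0.0807 (edgeR) over 152526 tested windows. At an unadjusted p under 0.05 the same authors' deposited table held 10816 windows with F1 higher and 12146 with F1 lower, 15.1% of those tested against 5% expected by chance. That 5% assumes no shift of fold changes with level. In this table the median log2 fold change went from 0.33 at mean F1 counts of 10 to 30 to -0.84 at 280 or more. The excess is therefore no count of windows that differ one by one. Of the windows named with F1 higher in the other tables, 869001 had the largest fold change here, 0.91 (edgeR, adjusted p = 0.0808 in the authors' deposited table). The others had 0.69 at 3631301, 0.51 at 2103601, -0.10 at 73236201, -0.28 at 33289301, -0.33 at 73086501 and -0.45 at 42442701 in the authors' deposited SnakeSide table. What the SnakeSide pools are is not given by the labels used here. At 73236201 the difference from the Lytle fold had an adjusted p of 2.89e-61 (approximate test on edgeR results), which may likewise be too small. The F1 and SnakeSide pools were still much closer to each other at this window than F1 and Lytle.

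**Figure D2:**
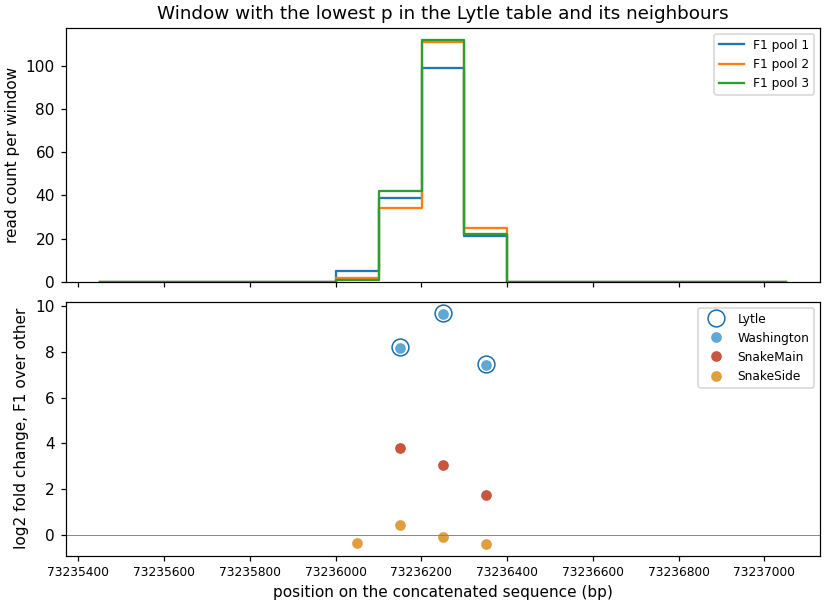
Read counts of the 3 F1 pools per 100 bp window (upper panel) and the authors' deposited log2 fold changes of F1 over each other set of pools (lower panel) around 73236201, against position in bp. F1 counts peak at 99, 111 and 112, and the fold change falls from 9.69 over Lytle to -0.10 over SnakeSide; windows without a point were not tested.

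Of the windows called over Lytle and tested in both tables, 60.5% of those with F1 higher and 53.7% of those with F1 lower were called over Washington in the same direction. The authors' deposited tables shared 2823 windows with F1 higher, against 154 for independent lists of that size, and 1962 with F1 lower, against 80.2. Only 2 windows were called in opposite directions. SnakeMain shared 463 higher and 119 lower windows with Lytle, where independent lists would share 26.3 and 7.42 of the authors' deposited calls. With Washington it shared 469 and 153, against 28.9 and 6.92. Called in the authors' deposited Lytle, Washington and SnakeMain tables alike were 403 windows with F1 higher, in 307 regions, and 95 with F1 lower, in 84 regions. Lists of the same lengths from simulated unchanged groups against the same F1 pools shared 938 higher windows (895 to 980 over 18 pairs) and 768 lower ones (734 to 824) for Lytle and Washington. They shared 243 (222 to 279) and 130 (107 to 144) for Lytle and SnakeMain, and 257 (233 to 293) and 126 (103 to 141) for Washington and SnakeMain. With pools 2 and 3 simulated as 1 library, the means over 9 pairs rose to 1033 and 872 for Lytle and Washington, 267 and 153 for Lytle and SnakeMain, and 285 and 149 (137 to 160) for Washington and SnakeMain. The lower windows that SnakeMain shared with Lytle (119) did not exceed either simulation, and those it shared with Washington (153) exceeded only the first. The overlaps of higher windows, and the lower ones of Lytle and Washington, lay above both. Part of that excess may come from the shared F1 pools, which are too few to be split. The simulated lists were filled by smallest p from groups that gave no call, so noise alone ranked their members. They were drawn from covered windows only, whereas the called lower windows included some with no read in any F1 pool. These simulated overlaps are therefore no baseline for called windows. They cannot decide whether the shared pools account for the lower windows that SnakeMain shared.

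Windows called higher in F1 in both the Lytle and the Washington table had a median log2 fold change of 0.78 in the authors' deposited SnakeMain table and 0.51 in the SnakeSide table. Of these windows 97.7% were positive over SnakeMain and 87.0% over SnakeSide, against 52.8% and 60.7% of all windows tested in the authors' deposited tables. In simulated unchanged groups, windows higher at an unadjusted p under 0.05 in both groups of a pair were positive in another group in 97.1% on average. Their median was 0.42, so a shared sign can come from the shared pools alone. Noise picked those windows at a looser threshold than the calls, so their share is no baseline for called windows. The 87.0% over SnakeSide lay below the lowest simulated share, 95.5%. Windows called lower in both tables had medians of -0.37 and -0.10 in the authors' deposited SnakeMain and SnakeSide tables, where all tested windows had medians of 0.03 and 0.16. Of these windows 89.7% were negative over SnakeMain and 60.8% over SnakeSide, against 47.2% and 39.3% of all windows tested in the authors' deposited tables. No simulated share was taken for lower windows, so these are given as values alone.

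Fold changes were most alike between Lytle and Washington. Over windows with a summed F1 count of at least 10, r in the authors' deposited tables was 0.775 for Lytle and Washington, 0.580 for Lytle and SnakeMain, 0.340 for Lytle and SnakeSide, 0.582 for Washington and SnakeMain, 0.364 for Washington and SnakeSide and 0.533 for SnakeMain and SnakeSide. Simulated unchanged groups gave an r of 0.500 from the shared F1 pools alone. With pools 2 and 3 simulated as 1 library it was 0.530. Unchanged groups of like spread set against 1 shared group give such an r by construction, so it is no yardstick for r between the tables. The covariance of the authors' deposited values was 0.400 for Lytle and Washington against a simulated 0.0765, leaving 0.323. The excess was 0.174 for Lytle and SnakeMain, 0.0869 for Lytle and SnakeSide, 0.180 for Washington and SnakeMain, 0.103 for Washington and SnakeSide and 0.143 for SnakeMain and SnakeSide. From a summed F1 count of 50 on, the excess over the simulated covariance was smaller: 0.140 for Lytle and Washington, 0.129 for SnakeMain and SnakeSide, 0.0712 for Washington and SnakeMain, 0.0628 for Lytle and SnakeMain, 0.0433 for Washington and SnakeSide and 0.0272 for Lytle and SnakeSide. The order of the pairs thus depends on the count minimum. Over the lower minimum, with pools 2 and 3 simulated as 1 library the shared covariance was 0.0952, still below each observed covariance, the smallest being 0.163. The simulated groups held no shift of fold changes with F1 count, whereas the authors' deposited tables did. Part of each excess may come from that shift.

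**Figure D3:**
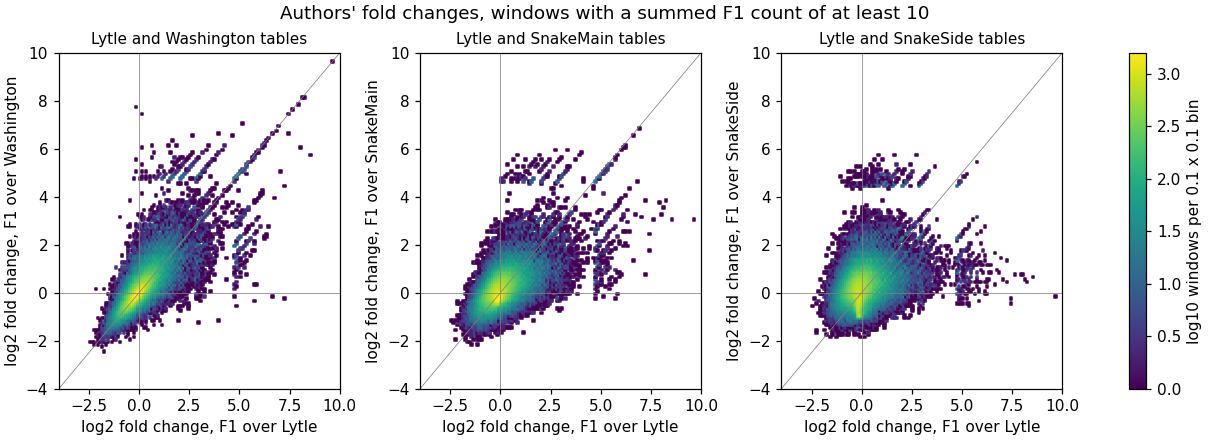
Each panel sets the authors' deposited log2 fold change of F1 over Lytle (x) against that over Washington, SnakeMain or SnakeSide (y), with colour for the log10 number of windows per bin; the grey diagonal marks equal values. The cloud is narrowest for Washington (r = 0.775) and widest for SnakeSide (r = 0.340), and fitted fold changes above 4 fall into separate bands.

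In windows called higher over Lytle the pools averaged 6.88, 6.75 and 6.33 CPM, and in windows called lower 5.91, 7.10 and 7.24 CPM, beside 6.18, 6.18 and 6.19 CPM in all windows tested in the authors' deposited table. For Washington the levels were 6.45, 6.42 and 6.04 CPM in higher windows and 7.17, 8.33 and 8.46 CPM in lower ones. The order of the pools was the reverse for SnakeMain, with 5.91, 6.70 and 7.03 CPM in higher windows and 12.6, 11.5 and 11.1 CPM in lower ones. Those lower windows averaged 12.0 CPM ± 0.910 (SD, n = 2) against 6.24 CPM in all windows tested. Of them 10.3% had a mean F1 count of at least 150, against 4.62% of all tested in the authors' deposited table. No window called higher over Lytle, Washington or SnakeMain had over 80% of its F1 count in 1 pool. Among windows called lower, 37 over Lytle, 43 over Washington and 3 over SnakeMain did, and 9, 15 and 2 had no read in any F1 pool. A pool stood at 0 in 6 of the 4664 windows called higher over Lytle and in 117 of the 3678 called lower.

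Fold changes moved with the F1 count. Between mean counts of 10 and 30, median log2 fold changes in the authors' deposited tables were 0.03 for Lytle, 0.07 for Washington, 0.19 for SnakeMain and 0.33 for SnakeSide. In the 434 windows with a mean count of at least 280, close to the highest possible count of 300, they were -0.11, -0.17, -0.35 and -0.84. From 10 to 30 counts to 60 to 100 counts the medians in the authors' deposited tables moved by -0.06, -0.14, -0.32 and -0.51 in the same order. The ratio of pool 2 to pool 1, from summed counts, moved by -0.32 log2 units over the same bands, and that of pool 3 to pool 2 by 0.01. A ratio of 2 single pools and a median of fitted group fold changes are unlike measures, so their steps are not on 1 scale. The 10 windows with 300 counts in all 3 pools lay between -0.93 and -0.99 in the authors' deposited SnakeSide table, each at its lowest adjusted p of 0.0807 (edgeR). At 300 counts an F1 pool could rise no further, so these values do not measure how far F1 lay below SnakeSide. Windows with far smaller unadjusted p had the same adjusted p. The unadjusted p was 0.000695 at 30509101 and 1.98e-06 at 1520301 (edgeR), so these 10 windows were not the strongest of that table.

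**Figure D4:**
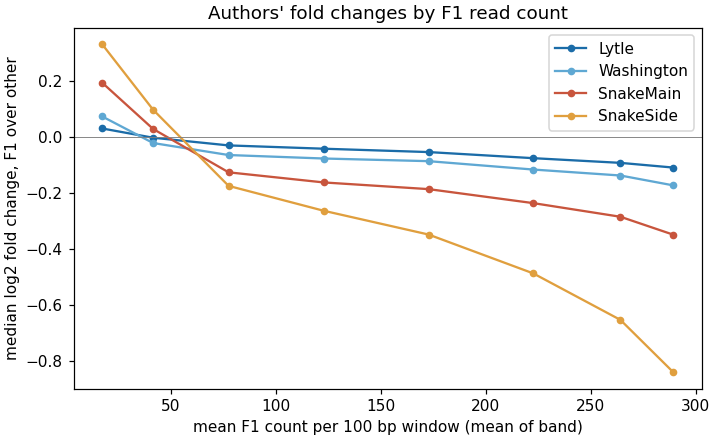
Points give the median of the authors' deposited log2 fold changes (y) of windows in bands of mean F1 count per 100 bp window (x, reads), with a line for each table. All lines end below 0, from -0.11 for Lytle to -0.84 for SnakeSide in windows with a mean count of at least 280.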

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

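The tests of the first pattern and the tests of the second on pools, libraries and foreign DNA were chosen after their values, or values close to them, had been seen; those on neighbouring windows and on the SnakeSide test were set down before. The samples form 1 group, so a difference in methylation was not tested as a cause.

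Fold changes of the same F1 pools differed between tables at single windows (approximate test of the difference from the authors' edgeR results, adjusted p under 0.05). Lytle and Washington differed in 12 windows, Lytle and SnakeMain in 17, Lytle and SnakeSide in 116, Washington and SnakeMain in 35, Washington and SnakeSide in 185, and SnakeMain and SnakeSide in 7. Simulated unchanged groups differed in 0, but they hold no changed windows, where the worked-back standard error is least certain. In the comparison of Lytle with SnakeMain the Lytle fold was the higher one in all 17. Against SnakeSide the Lytle fold was higher in 97 of 116 and the Washington fold in 155 of 185.

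The first pattern is the fall of F1 fold changes in the most covered windows, most of all over SnakeSide. A ceiling of 1 read per start and strand cannot be told apart from other causes: the raw count ratio of pool 2 to pool 1 was 1.03 at mean counts of 280 or more, but with no count above 300 that ratio cannot exceed 1.25 there, whatever the cause. Most of the decline in the ratio came at lower counts, from 1.55 at 10 to 30 through 1.37 at 30 to 60 to 1.20 at 60 to 100. In the 10 windows at 300 counts in all 3 pools the F1 count could rise no further. Their folds over SnakeSide lay between -0.93 and -0.99. A ceiling in both sets of pools would give so narrow a range, but the counts of the SnakeSide pools were not used. From 10 to 30 counts to 60 to 100 counts the median fold changes moved by -0.06 log2 units for Lytle, -0.14 for Washington, -0.32 for SnakeMain and -0.51 for SnakeSide. Enrichment that differs from library to library stays open too. Within the F1 group, summed counts changed by -0.32 log2 units over the same bands for pool 2 over pool 1 and for pool 3 over pool 1. For pool 3 over pool 2 they changed by 0.01, so the step rests on pool 1 alone. The SnakeMain step was of about that size and the SnakeSide one larger. Medians of fitted group fold changes and ratios of 2 single pools are unlike measures, so this order decides nothing.

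The second pattern is a set of 131 windows, in 95 regions, called with F1 at least 16-fold above both Lytle and Washington (log2 fold change of at least 4), against 3 windows with F1 as far below both. The median mean F1 count was 5.33, so many of these fitted folds may depend on the prior count. In 0% of them did 1 pool hold over 80% of the F1 count, which says nothing of a library that pools 2 and 3 share. With both taken as 1 library, 6.11% (8 windows, none of them in favour of pool 1) had over 80% of the F1 CPM in 1 library. The set was selected by a test that treats the pools as replicates, which hardly calls a window carried by 1 pool. No window called higher over Lytle or Washington had over 80% of its F1 count in 1 pool. These shares therefore cannot decide whether 1 library was the source of the 131 windows. Over SnakeMain the median was 3.81 (quartiles 2.73 and 4.88) and 52 of them were called, but DNA of another organism in the F1 pools alone would leave the fold over SnakeSide as high, and its median there was 0.92 (quartiles 0.47 and 1.49). Sequence missing from the Lytle and Washington snails could not be told apart from a loss of methylation, and no unenriched DNA was used here. Of 21 covered neighbours outside the set, 14.3% also reached 4 over Lytle, which is between the bounds set for each. Neighbours that belonged to the set were left out of this share, which lowers it, so it cannot decide.

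The third pattern is the absence of calls over SnakeSide beside 8342 over Lytle and 8554 over Washington. Lower power may account for it: at a log2 mean CPM of 2 to 4 and an absolute log2 fold change of 1 to 1.5, the median unadjusted p was 19.4 times that of the Lytle table (0.00878 against 0.000452), and in the SnakeMain table it was 5.90 times that of Lytle. Smaller fold changes cannot be told apart as a further cause: after centring by level, 3.53% of SnakeSide windows reached an absolute log2 fold change of 1 against 5.14% for Lytle, between the bounds set beforehand. The share was lower still for SnakeMain, 2.87%, and that table held 1192 calls. The count of 0 is therefore no measure of how alike F1 and SnakeSide were.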

How the results depend on the processing

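Of 103 alternative values, 59 stayed the same, 44 moved and 0 reversed. Some of the 59 were fixed in advance: centred r, stricter subsets and regions of the SnakeSide list of 0, and F1 levels without pool 1. The tally is therefore no measure of stability. A count was taken as the same within 1.5 times the main count. Other values were so within 1 SD between pools, pairs of pools or leave-one-out fits, or within the 95% interval of a median or r over windows, so tolerances differ between results. Those named as added were chosen after seeing the data. The coefficient of variation between pools ranged from 0.00988 to 0.115 when 1 pool was left out, and fell only without pool 1, because pools 2 and 3 are alike; with both summed (added) it was 0.124. Mean r between pools, 0.950, was 0.913 with log2(CPM + 0.1), 0.978 over all windows, 0.926 without the highest 1% of windows and 0.749 below a summed count of 90 (added), as a narrower range of levels gives.

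Called windows followed the threshold by construction. At an adjusted p under 0.1 they numbered 12897 for Washington, 2635 for SnakeMain and 5586 for SnakeSide. At an adjusted p under 0.01 they were 3831 for Lytle, 3835 for Washington and 326 for SnakeMain. At an unadjusted p under 1e-05 they were 1510, 1598, 258 and, for SnakeSide, 11, all with F1 higher. Under 1e-06 they were 854, 895 and 122. With an absolute log2 fold change of at least 1, Lytle kept 5119 and Washington 5326. The SnakeSide count of 0 thus held at an adjusted p under 0.01 but not at 0.1. Regions of at least 2 called windows numbered 2026 for Lytle, 2106 for Washington and 204 for SnakeMain. Leaving out windows with a mean F1 count of at least 150 (added) moved no count by over 1.5 times.

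In windows above the median level of a table, median log2 fold changes lay nearer to 0: 1.04 and -0.87 for Lytle, 1.11 and -0.83 for Washington, 1.28 and -0.75 for SnakeMain. Calls at an unadjusted p under 1e-05 had a mean F1 level of 8.79 CPM (higher) and 7.58 CPM (lower) for Lytle, 8.37 CPM (higher) for Washington and 9.26 CPM (lower) for SnakeMain; the cause was not tested. At that p the tables shared 879 windows for Lytle and Washington, 129 for Lytle and SnakeMain, 125 for Washington and SnakeMain and 1 for Lytle and SnakeSide. Lytle and Washington shared 3035 regions. From a summed F1 count of 50 on, r was 0.869 for Lytle and Washington, 0.518 for Lytle and SnakeMain, 0.234 for Lytle and SnakeSide, 0.540 for Washington and SnakeMain, 0.292 for Washington and SnakeSide and 0.744 for SnakeMain and SnakeSide; the cause was not tested. Centring each table cannot change r and says nothing. Alternatives on CpG content and genomic features were not run. No paired analysis was possible because the samples form 1 group. Small changes can be missed: over all covered windows, 31.3% of simulated changes of 1 log2 unit were called. Few windows were changed in that simulation, which made its cutoff on the unadjusted p stricter than in tables with many calls. The share therefore does not give the power of the authors' tests.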

Other observations

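The tests named here were chosen after the data had been seen. Windows called higher over Lytle, Washington and SnakeMain alike were mostly positive over SnakeSide too, although none passed the test there: 96.3% of 403 windows, with a median log2 fold change of 0.81 in the authors' deposited table. Of the 95 windows called lower in the same tables, 98.9% of the 93 with a value were negative over SnakeSide, with a median of -0.60. Simulated groups share their signs through the F1 pools, so these shares are given as values alone.

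At an adjusted p under 0.1 the authors' deposited SnakeSide table held 1544 windows with F1 higher and 4042 with F1 lower, whereas the 11 windows at an unadjusted p under 1e-05 all had F1 higher. Of the lower ones 42.1% had a mean F1 count of at least 150, against 4.81% of all windows tested in that table. The lowest p of the SnakeSide table fell at 1520301 to 1520400, with 10, 20 and 17 F1 reads and a log2 fold change of 3.02. Over Lytle, Washington and SnakeMain its values in the authors' deposited tables were 0.90, 1.76 and 1.45, and the one over Washington passed the test (edgeR, adjusted p = 0.00367). The next, at 12297101 to 12297200, had 15, 20 and 19 reads and 2.28 in the authors' deposited table, but 0.28, 0.21 and 0.23 over Lytle, Washington and SnakeMain. Both were chosen after their values were seen, and neither passed the adjusted test (edgeR, adjusted p = 0.0807 for each).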
